A study of Mus musculus with 9 samples.

How the data were processed

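Single-cell RNA was measured in whole kidneys of 9 mice, with 1 library per mouse. By the labels, 4 libraries came from wild-type mice, 2 from OVE26 mice and 3 from OVE26 mice lacking Lrg1. Per the labels' protocols, glomeruli were pulled out of each kidney with magnetic beads, the glomerular and remaining fractions were dissociated apart, and both were pooled again for each mouse. The remaining fraction was digested for 10 min at 37°C and passed through 40-micron strainers. Libraries were made with the 10x Genomics Chromium 3′ kit (v3), which tags each captured transcript with a unique molecular identifier (UMI), and were sequenced to a target of at least 30000 reads per cell. This preparation sets how often each cell type appears, so no share of cells given here is the share of that type in the intact kidney.

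The authors deposited 1 matrix of whole-number counts, as its file header states, with 1 line for each gene row and cell column where the count was above 0. The submitters' processing notes name Cell Ranger, Seurat and the build mm10, without versions or roles. The aligner, the annotation, the ambient RNA treatment and the doublet treatment are not given in the sources used here. The values hold traces of a filter on cells. No cell had fewer than 500 UMIs, and no cell had 200 or fewer or 6000 or more detected gene rows. The row and column positions are plain numbers, and neither a list of gene names nor a map from cells to libraries was used here. Row order, column order and expression values were not used in place of such a list or map. The matrix was therefore treated as 1 pooled sample. Positions in the genome are not reported, because they need the gene names.

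Before the data were examined, 3 comparisons were planned: OVE26 with wild type, OVE26 Lrg1-/- with OVE26, and OVE26 Lrg1-/- with wild type. Each was to sum counts per library in 4 main cell classes, to test lists of genes fixed in advance, and to compare shares of cell types. All of these need gene names or the library of each cell, so they are not analysed here, and the rule for naming genes names none. Cell types are not named either, since the markers fixed in advance are gene symbols. What follows describes the pooled matrix. Its methods were chosen after the form of the matrix was known.

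Counts of each cell were scaled to a total of 10000 and log-transformed after adding 1, leaving out rows seen in fewer than 10 cells. The 2000 most variable rows were scaled, with values limited to 10, and reduced to 30 principal components. Cells were joined to 15 neighbours and clustered by the Leiden method at a resolution of 1.5. Scanpy 1.11.5, igraph 0.11.9, NumPy 2.4.6, SciPy 1.17.1, scikit-learn 1.9.0 and Python 3.11.15 were used. No integration across libraries was applied. The planned filter on mitochondrial counts and the planned removal of doublets per library were not applied, and doublets, if any remain, are in the clusters. A gene row was called leading in a cluster when its pooled CPM (counts scaled to a common total) were at least 4 times those of all other cells and it was seen in at least 25% of the cluster's cells. Where other cells held fewer than 3 counts of a row, 3 counts were used in their place. The same rule was applied between pairs of clusters, and a cluster was called distinct from another at 20 or more such rows of its own. This is a one-way count. A cluster's nearest was the other cluster against which it had the fewest such rows, and similarity was not measured otherwise. For joining clusters both directions were counted, and a pair was linked only if neither had 20 rows above the other. Clusters linked through a chain of such pairs were joined.

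Leading rows were called in clusters drawn from the same cells and counts, so they are not independent findings. To see how far they rest on counting noise, the counts of every cell were divided at random into 2 parts. Clusters were drawn and leading rows were called in one part, and the folds of those rows were measured in the other. Both parts come from the same cells, so free RNA, doublets and differences between libraries are in both. Detected rows per cell depend on depth, so they were also counted after thinning every cell to 500 UMIs, which left out no cell. The procedure was tested on simulated data of 1800 cells in 3 populations with the mean profile of the real matrix. The 200 changed rows were drawn at random from rows seen in at least 10 cells, and leading rows were called with the true populations. Of 66 rows raised 8-fold, 33 were called, and of 66 raised 16-fold, 41 were called. Every row missed at these folds was seen in under 25% of its population's cells, so the rule misses sparse rows even when they change strongly. Of 68 rows raised 2-fold, which is under the threshold, 0 were called, but only 11 were seen in at least 25% of their population's cells. Among 3568 unchanged rows seen often enough to be called, 0 were called. The simulated cells of a population shared a profile and differed only in depth and counting. These results therefore give no false-call rate for the real clusters, which were drawn from the same counts. Clustering the same simulated cells at a resolution of 0.3 gave 4 clusters for the 3 populations, with an adjusted Rand index of 0.467. This was 1 simulation at a resolution other than that of the real data, and why the populations were only partly recovered was not tested. Shares of cells have exact binomial (Clopper-Pearson) 95% intervals. These cover counting error only and say nothing about the spread between mice, which cannot be measured in 1 pooled sample. No p-value between cells or clusters is given. Alternatives were another resolution, more variable rows, another random seed, a stricter cell filter, removal of the most abundant rows, and clustering on part of the counts.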

Results

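The series concerns diabetic kidney disease in OVE26 mice, a transgenic line with type 1 diabetes, and the effect of deleting Lrg1 in that line. Lrg1 encodes leucine-rich alpha-2-glycoprotein 1, a secreted protein that modulates TGF-β signalling in endothelial cells. Kidney cells of 4 wild-type, 2 OVE26 and 3 OVE26 Lrg1-/- mice were profiled. The counts of all 9 libraries were read as 1 pooled matrix with no cell assigned to a library. The effects of diabetes and of Lrg1 loss, and the level of Lrg1 itself, are not analysed here. The cell populations below are described by number, for all mice together.

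The matrix held 53100 cells and 21181 gene rows, with 529600641 UMIs in 115823394 entries above 0. Of all row-by-cell positions, 89.7% were 0. The number of UMIs per cell ranged from 500 to 69178 with a median of 5717, and the quartiles were 2173 and 14343. A median of 1829 gene rows was detected per cell, with a range of 201 to 5999. There were 6073 cells (11.4%) with fewer than 1000 UMIs and 8596 cells (16.2%) with more than 20000. No 2 cells had identical counts.

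**Figure D1:**
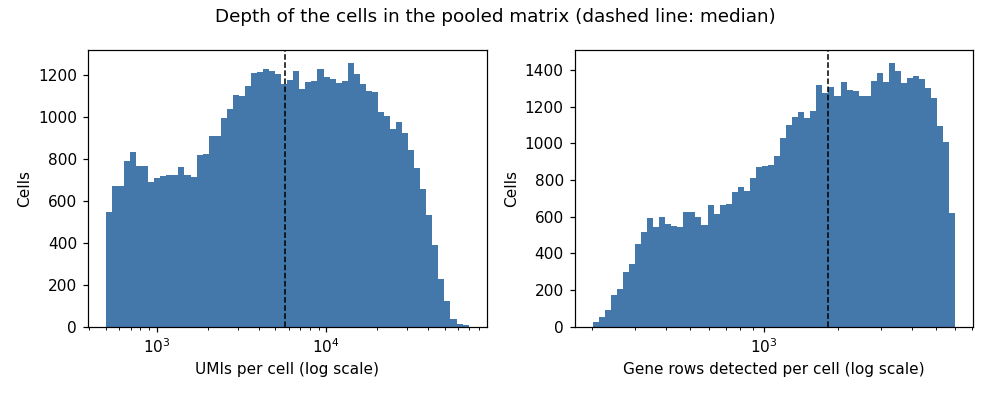
Histograms of the UMIs per cell (left) and the gene rows detected per cell (right) for all 53100 cells, both on a log axis, with the number of cells on the vertical axis and a dashed line at the median. The medians were 5717 UMIs and 1829 gene rows, and UMIs per cell ended sharply at 500 on the left.

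A small number of gene rows held much of the RNA. The 10 most abundant rows took 33.6% of all UMIs, and the single most abundant row took 6.80% and was seen in 53099 of the 53100 cells. The 110 most abundant rows held 50% of all UMIs. The share of a cell's UMIs in the 10 most abundant rows had a median of 33.4%, with 5th and 95th percentiles of 10.4% and 47.7%. Across the clusters described next, the median of this share ranged from 9.60% to 39.1%. At the other end, 2538 rows were seen in fewer than 10 cells, and 9 were seen in none.

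Clustering divided the cells into 39 clusters, numbered by size. The largest, cluster 1, held 4389 cells, or 8.27% (95% interval 8.03 to 8.50), and the 5 largest held 32.5% together. The smallest, clusters 38 and 39, held 44 and 43 cells, and 13 clusters each held less than 1% of the cells. In all, 4034 gene rows (19.0%) led at least 1 cluster, of which 1837 led exactly 1. In the same clusters, a random 0.5 of the counts gave 2792 such rows, and it gave 2475 when the clusters were redrawn from it as well. The number of leading rows per cluster ranged from 0 in clusters 1 and 4 to 772 in cluster 20, with a median of 170. This number can be low because other clusters share the same rows, since all other cells are the reference. It can also be low in shallow cells, since a leading row must be seen in 25% of the cluster's cells. Depth was not matched between clusters for this number. Row 5172 had the highest fold in clusters 3, 9 and 10, and was seen in 16.2%, 16.7% and 16.7% of their other cells.

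The clusters differed in the number of leading rows against all other cells. At the high end, 22 clusters, each with at least 100 leading rows, together held 14778 cells, or 27.8% of all. Cluster 6 (2851 cells, 5.37%, interval 5.18 to 5.56) had 542 leading rows. Its leading row of highest fold, row 11460 of the matrix, stood at 3068 CPM (pooled counts scaled to a common total) against 2.82 in other cells. It was seen in 97.0% of the cluster's cells and 1.40% of the others. Cluster 14 (1884 cells, 3.55%, interval 3.39 to 3.71) had 323 leading rows. Its leading row of highest fold, row 2244, stood at 7794 CPM against 38.3, and was seen in 99.9% of the cluster's cells. It was also seen in 9.13% of all other cells, the highest such share among the 22 clusters. Free RNA in the droplets, doublets and low expression are not told apart by that share.

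Some clusters had few rows of their own that set them above at least 1 other cluster. There were 16 clusters, with 37164 cells or 70.0% of the total, that had fewer than 20 leading rows against their nearest cluster, and 8 of these had 0. This count goes one way only, since the nearest cluster may still have 20 or more rows above the cluster in question. Clusters 14 and 24 were among the 16, with 17 and 9 rows above their nearest, and both remained separate when both directions were counted. Clusters 2 and 12, with 13 and 14 rows, had as their nearest cluster 39, which held 43 cells. Clusters 4, 5 and 18, with 0, 11 and 3 rows, had as their nearest cluster 35, which held 162 cells. Against such small clusters, the floor of 3 counts keeps low rows from being called. How far it lowered these counts of rows was not tested. The median depth of these 16 clusters ranged from 769 to 27162 UMIs. Of the 8 clusters with 0 rows, all but cluster 10 had a lower median depth than their nearest. A row must be seen in 25% of a cluster's own cells, so shallow clusters have fewer rows that can be called. Depth was not matched between clusters in these counts. Clusters 1, 3, 4, 7, 8, 10, 11 and 13 formed a single group when clusters were joined wherever neither of a pair reached 20 rows against the other. The joining goes through chains, so members linked only through others may still reach 20 rows against each other. This group held 22600 cells (42.6%), with median depths from 1068 UMIs in cluster 1 to 10630 in cluster 7. The joining left 32 groups in place of 39 clusters, and no other clusters were joined.

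**Figure D2:**
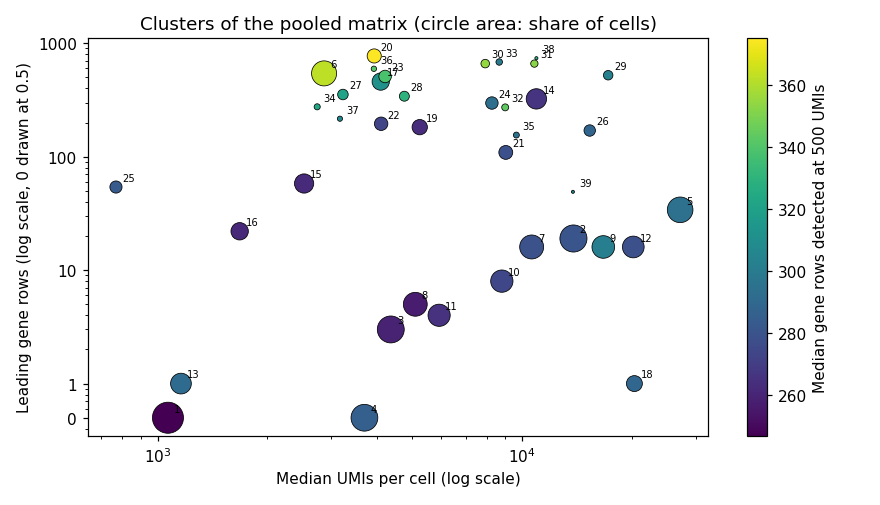
Each circle is 1 of the 39 clusters, with median UMIs per cell on the horizontal log axis, the number of leading gene rows on the vertical log axis (0 drawn at 0.5), circle area proportional to the share of cells, and colour giving the median gene rows detected after thinning each cell to 500 UMIs. Clusters 1 and 4 are large circles with 0 leading rows, while cluster 20 has 772 leading rows and the highest thinned detection, 375 rows.

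Clusters also differed in how many rows their RNA was spread over at equal depth. After every cell was thinned to 500 UMIs, the median number of detected rows was 282 over all cells and ranged from 247 in cluster 1 to 375 in cluster 20. Before thinning the same clusters had medians of 483 and 1868 rows, at median depths of 1068 and 3932 UMIs. Cluster 6, at 2864 UMIs, detected 362 rows after thinning, more than the 294 of cluster 5, whose cells had a median of 27162 UMIs. The 10 most abundant rows took a median of 16.5% of UMIs in cluster 6 and 14.0% in cluster 20, against 39.1% in cluster 1 and 33.2% in cluster 5.

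The leading rows were measured again on counts that had not been used to draw the clusters. Clusters drawn from one part of the counts numbered 39 and had 4741 pairs of a cluster and a leading row. In the other part, 4610 of these pairs (97.2%) again reached 4-fold, and the median fold was 10.38 against 10.47 in the part used for clustering. Pairs of all clusters were pooled, so clusters with many leading rows weigh most in these values. The rule of detection in 25% of cells was not applied again to these pairs. In the other part, 17 of these 39 redrawn clusters had at least 20 leading rows against their nearest cluster. Because both parts come from the same cells, the repeat of the folds speaks to counting noise only. The assignment of single cells was less stable, with an adjusted Rand index of 0.565 between these clusters and those from all counts, where 1 is identity.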

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

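The alternatives planned before the data were examined all concern comparisons between libraries or named genes, which are not analysed here, so none was run as planned. No paired analysis was possible because no cell was assigned to a library or replicate number. The alternatives below were chosen after seeing the data. With all counts, the number of clusters was 39 and lay between 28 and 42 under the 6 alternatives. Rows leading a cluster numbered 4034, and between 3094 and 4106 under 5 alternatives. Both clustering and measuring on a random 0.5 of the counts gave 2475. With only the measuring on that part it was 2792, and with only the clustering on it 3631. At each setting the largest cluster was taken anew, so it need not hold the same cells. The share of cells in the largest cluster was 8.27%. It was 10.13% at a resolution of 0.8, 6.72% with 4000 variable rows, 7.40% with another random seed, 7.87% among the 46863 cells with at least 500 detected rows, 6.61% without the 10 most abundant rows, and 7.82% on part of the counts, so it depends on the setting by more than its counting interval. Clusters with 20 or more rows of their own above their nearest (a one-way count) numbered 23, and 17 to 23 under the alternatives. Both clustering and measuring on a random 0.5 of the counts gave 17 such clusters. With only the measuring on that part there were 21, and with only the clustering on it 18. The adjusted Rand index to the reported clusters ranged from 0.565 (part of the counts) to 0.869 (another random seed). Rows seen in under 25% of a cluster's cells cannot be called leading, so sparse rows are missed.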

Other observations

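The order of the cells in the matrix was not used to assign any library, but it was examined for structure. The test of depth against random order was chosen after the result was seen. For the tests on cluster makeup, what each outcome would mean was written before the result was seen.

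Depth varied along the matrix. Over 53 stretches of 1000 consecutive columns, median UMIs per cell ranged from 3928 to 9006, and the standard deviation of the stretch medians was 0.301 on the log2 scale. In 1000 shuffled orders it was at most 0.113, which argues against a random order of the cells (permutation p = 0.001, one-sided, the smallest that 1000 shuffles can give). Different shares of the 39 clusters do not account for all of it, since the standard deviation was 0.222 after each cluster's median was subtracted, against at most 0.056 in shuffled orders. Cluster makeup also varied, with a chi-square of 20.27 per degree of freedom against at most 1.10 in shuffled orders, and cluster 4 ranged from 0 to 17.6% of a stretch. Rows were also compared within 17 of the 39 clusters, those with at least 50 cells in 2 or more stretches. There, 25 gene rows were seen in at most 5% of the cells of one stretch and at least 50% of another. The count was 0 rows when the cells of each cluster were shuffled, which was done 1 time only. Depth was not matched in that count. A candidate explanation is that the libraries were joined end to end and differ in depth and content, but no stretch was tied to a library, so neither a library batch nor genotype was tested.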
